A study of Mus musculus with 6 samples.

How the data were processed

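Bulk RNA-seq was available for 6 libraries of mouse embryonic stem cells, 3 labelled wild type and 3 labelled Yaf2KO. Per the labels' protocols, the cells grew on mitomycin-inactivated embryonic fibroblasts with serum and leukemia inhibitory factor, RNA was extracted with TRIzol, and libraries were made from poly-T selected mRNA with a NEBNext Ultra kit. Each deposited file holds raw read counts per gene for 1 library, per the file headers, next to gene coordinates and annotation. The submitters' processing notes name TopHat2 2.0.12, Cufflinks 2.2.1, HTSeq 0.6.0 and the genome build mm10, without their roles. The notes used here state no strand setting, so reads of antisense and overlapping genes cannot be told apart, and reads of pseudogenes and close paralogues are uncertain. Poly-T selection also captures RNA without a poly-A tail poorly.

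Every file lists the same 1653 genes, a part of the transcriptome. How these genes were chosen is not given in the sources used here. The sum of the listed genes ranged from 56367 to 451075 counts and is not the depth of the library; library totals were not used here. For that reason no interval for a share of a library is given, and no fold change on the scale of the whole transcriptome. Counting noise is still known for each gene from its raw count, which is printed per library for the genes named. Of the listed identifiers 1640 were found in GENCODE vM21 (GRCm38, the mm10 assembly), 1406 of them with identical coordinates, and gene types were taken from that annotation. Gene symbols of the fixed lists were matched through it and the reference name tables; 1 germline member, 1700123I01Rik, matched only through a synonym.

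Groups and replicate numbers came from the sample titles and genotype labels. No label says that the replicates are separate cultures or clones, so the p-values measure only the spread between these samples, which may be technical. Chi-square tests of counts over genes with at least 20 reads found no pair of libraries that agreed within sampling noise (chi-square per degree of freedom at least 5.01), so each library counted as 1 replicate.

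The comparison used edgeR 4.0.16 (R 4.3.3) with quasi-likelihood fits (glmQLFit robust, glmQLFTest), TMM factors, filterByExpr by genotype and Benjamini-Hochberg adjustment at 0.05; calls were also counted at an absolute log2 fold change of at least 1. On a partial list TMM sets the typical listed gene to no change, and the fold changes are relative to it. TMM factors ran from 0.923 to 1.08. The filter left 376 genes. Standard errors come from the fitted model. CPM values are relative to the TMM-scaled sum of the listed genes, not to the whole library. Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, two-sided) over the 9 lists with at least 3 tested members. No enrichment of the list against the genome was computed, because the genes that could have entered it are unknown.

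Counts were simulated with the means, library sums and common dispersion (0.253) of these libraries, with 200 genes changed before filtering. Of the tested genes edgeR called 23 of 24 at a true 8-fold increase and 8 of 18 at 4-fold, 8 of 8 at 0.125-fold, 7 of 10 at 0.25-fold and 2 of 339 unchanged genes. With 0 genes changed it called 0 of 382. In this simulation a relative increase under about 4-fold was therefore mostly not detectable. The simulation gave every gene and both genotypes the same dispersion, whereas fitted apart it was 0.106 in wild type and 0.363 in Yaf2KO. The detection rates may therefore be too high for the real libraries. There Halr1 and Fgf5, with fitted log2 fold changes of 3.27 and 3.18, were not called.

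The design, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Yaf2 and Rybp, then called genes with separate groups, a mean CPM of at least 5 and a regular symbol (the 12 largest changes and 5 smallest p-values per direction). For each list it names up to 4 called members or, with 0 called, the 2 with the highest mean, and called genes within 500 kb of Yaf2. Genes outside the rule are said to be named after their values were seen; in the lists, members beyond the rule are given as examples. The values of 1 further gene are not reported here. Alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a mean CPM of at least 1, the replicate number as a block, each library left out, an adjusted p under 0.01, camera with an estimated correlation, and fry. Equal depth, scaling to the sum of the listed genes and leave-one-out values of the raw count comparisons were added after the data were seen. Per-library list values used log2 of scaled counts plus 1 and members with a mean count of at least 10. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.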

Results

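RNA was sequenced from mouse embryonic stem cells of 2 genotypes, wild type and Yaf2KO, with 3 libraries each. Embryonic stem cells are self-renewing cells taken from the early embryo that can form all tissues of the body. Here they grew with leukemia inhibitory factor and serum on inactivated mouse embryonic fibroblasts, and the Yaf2KO cells were made with Cas9. YAF2 is a paralogue of RYBP and a subunit of variant Polycomb repressive complexes 1, which monoubiquitinate histone H2A at silent developmental genes. The study's title names gene regulation by Yaf2 as its subject, and the single contrast is Yaf2KO against wild type.

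The rows analysed here are raw read counts of 1653 genes, the same genes in every library. They are a part of each library, so their sum is not the sequencing depth, which was not used here. The listed genes summed to 65595, 56367 and 72975 counts in wild type 1 to 3 (64979 ± 8321, SD, n = 3). They summed to 451075, 251141 and 143682 in Yaf2KO 1 to 3 (281966 ± 155998, SD, n = 3). By reference annotation 808 of the listed genes are protein-coding and 832 belong to other types, among them 175 long intergenic non-coding RNAs, 154 antisense RNAs and 217 pseudogenes of all kinds. Counts are low for many of them: 469 genes have fewer than 10 reads over the 6 libraries together, and 15 have 0. How the genes of the list were chosen is not given in the sources used here.

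Yaf2 itself (15:93284278-93336935, minus strand, mm10) is not among the rows used here, and neither is its paralogue Rybp, so the target transcript could not be compared between the genotypes. Of the 16 genes annotated within 500 kb of Yaf2, 4 of them protein-coding, 0 are among the listed genes, so effects on its neighbours were not analysed here either.

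The listed genes had higher counts in Yaf2KO nearly throughout. Slc2a3, a glucose transporter gene and the listed gene with the most reads, had 10080, 8630 and 8236 counts in wild type and 53271, 33920 and 28258 in Yaf2KO. The pluripotency factor Nanog had 2239, 1750 and 2756 counts in wild type and 20052, 8710 and 2816 in Yaf2KO, and the PRC1 subunit Bcor 892, 792 and 620 against 4796, 2683 and 837. Summed over the 3 libraries of a genotype, 1524 of the 1653 genes had more reads in Yaf2KO, 70 had fewer and 59 had equal sums. Among the 161 genes with a mean count of at least 100 all 161 had more, with a median log2 ratio of 2.18 (lowest 0.85, highest 5.99). In 453 genes every Yaf2KO count lay above every wild-type count and in 0 genes the reverse held; chance separates 3 libraries from 3 in 10% of genes, 5% each way. Yaf2KO 1 held most of the excess: 80.2% of the listed genes exceeded every wild-type library there, 63.2% in Yaf2KO 2 and 37.0% in Yaf2KO 3. Without Yaf2KO 1, the median log2 ratio of group means for the 161 genes was 1.41, with 158 higher and 3 lower, the number of listed genes with a higher mean count in Yaf2KO was 1302, and without Yaf2KO 3 the number with complete separation was 884. These counts are not corrected for depth, which was not used here.

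**Figure D1:**
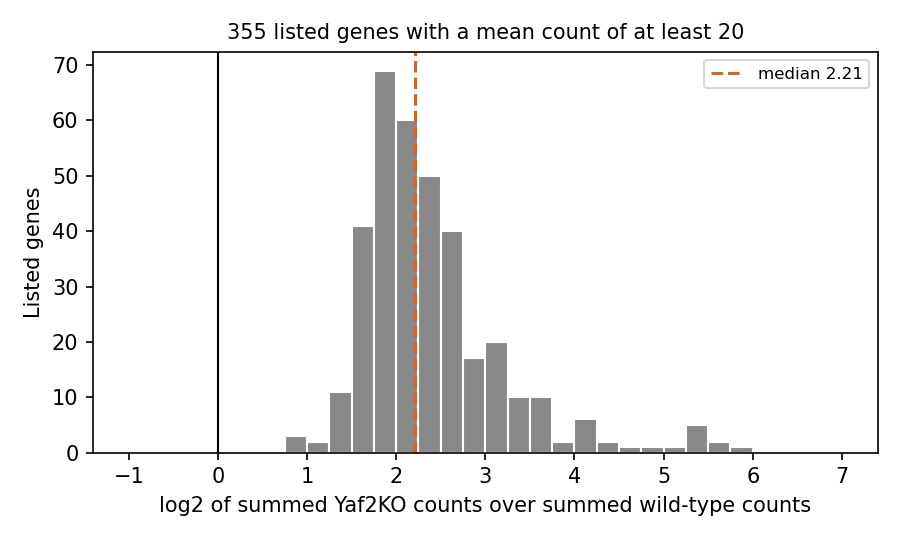
Distribution over 355 listed genes (mean count of at least 20 over the 6 libraries) of the log2 ratio of summed Yaf2KO to summed wild-type counts (x axis, log2 units, not corrected for depth), with the number of genes on the y axis. All 355 ratios lie above 0, with a median of 2.21 (dashed line).

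Because library totals were not used here, genes were compared with one another: each library was scaled on the listed genes, so a log2 fold change of 0 is the change of the typical listed gene. On this scale 3 of 376 tested genes rose in Yaf2KO above the rest of the list and 0 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Lef1, a DNA-binding effector of WNT signalling that also marks the primed epiblast, had 9, 5 and 12 counts in wild type and 1315, 208 and 131 in Yaf2KO. Its log2 fold change was 3.51 (SE 0.64, adjusted p = 0.0434 by edgeR, higher in 3 of 3 Yaf2KO libraries than in every wild-type library). Csn3, which encodes the milk protein kappa-casein, rose by 3.49 (SE 0.67, adjusted p = 0.0434 by edgeR), from 3, 3 and 5 counts to 136, 162 and 134. Wnt8a, a WNT ligand of the gastrulating embryo, rose by 3.23 (SE 0.55, adjusted p = 0.0434 by edgeR), from 7, 3 and 4 counts to 335, 183 and 82. In scaled values Lef1 went from 131 ± 43.5 to 1506 ± 1045 CPM of the listed counts (SD, n = 3 each), Csn3 from 56.2 ± 14.2 to 643 ± 365 and Wnt8a from 71.3 ± 28.9 to 677 ± 53.1. All 3 changed at least 2-fold. At an unadjusted p under 0.05 there were 16 genes, 15 higher and 1 lower. The lower one, Gm43482, is named because it is alone; it had 9, 6 and 31 counts in wild type against 57, 14 and 8.

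In the annotation Lef1 lies on chromosome 3 (131110471 to 131224356, plus strand), Csn3 on chromosome 5 (87925579 to 87932665, plus strand) and Wnt8a on chromosome 18 (34542313 to 34548273, plus strand), in mm10 coordinates. The values are sums over each whole gene, so they do not tell exons, introns or isoforms apart.

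**Figure D2:**
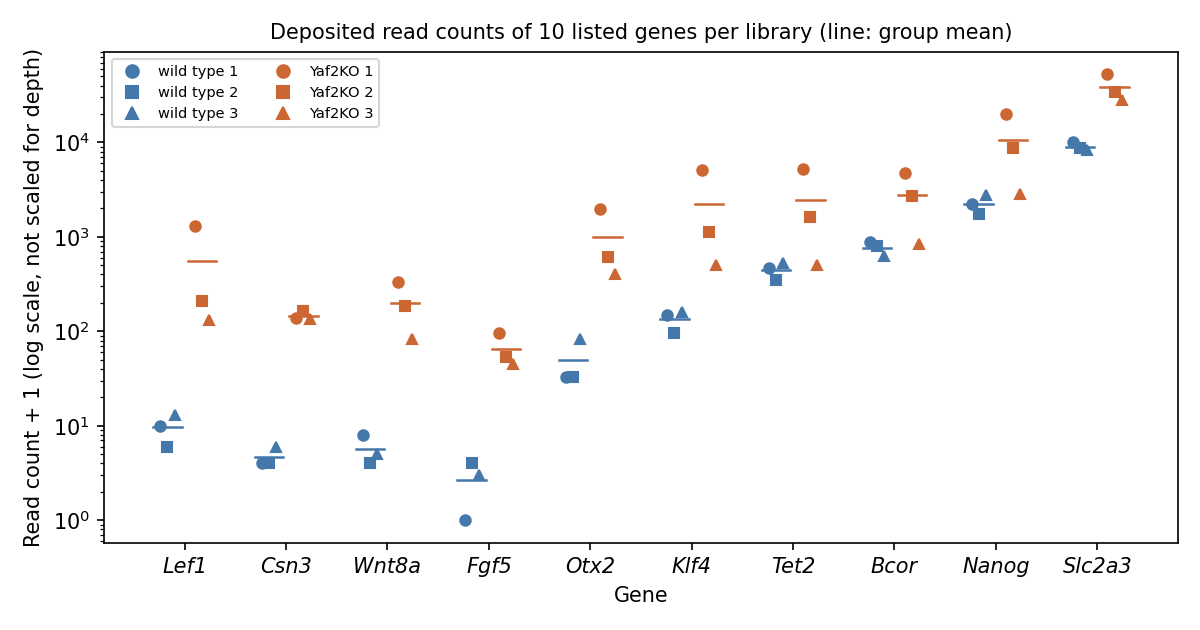
Deposited read counts plus 1 (y axis, log scale, not corrected for depth) of 10 listed genes (x axis) in each of the 3 wild-type (blue) and 3 Yaf2KO (orange) libraries, with a symbol per replicate and a line at the group mean. For Lef1 the wild-type counts are 9, 5 and 12 and the Yaf2KO counts 1315, 208 and 131, whereas for Nanog Yaf2KO 3 (2816) lies close to wild type 3 (2756).

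The calls depended on single libraries. Leaving out wild type 1, 2 or 3 left 0 calls each, leaving out Yaf2KO 2 left Lef1 alone, leaving out Yaf2KO 3 left Lef1 and Wnt8a, and leaving out Yaf2KO 1 gave 11 calls, 9 higher and 2 lower, with Lef1 at a log2 fold change of 2.75. DESeq2 called 10 genes on the same 376 (all higher) and limma-voom 0 (14 at an unadjusted p under 0.05). With all libraries taken as equally deep, in place of scaling on the list, 314 of 415 tested genes (75.7%) were called by edgeR, all higher. The median log2 fold change of the tested genes is then 2.12, and over genes tested both ways the scalings differ by 2.16 log2 units (4.46-fold); this alternative was added after the data were seen.

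Primed epiblast genes, which mark the pluripotent cells of the embryo after implantation, had the smallest camera p of the 9 lists tested, with the third highest median. Of 20 fixed symbols 9 were among the listed genes, all 9 with more reads in Yaf2KO, and 8 could be tested. The list lay above the other listed genes (camera, adjusted p = 0.000105, median log2 fold change 0.72), but not when the correlation between its genes was estimated from the data (adjusted p = 0.304 with an estimated correlation) nor by fry (adjusted p = 0.188). With single libraries left out it stayed past the threshold in each case by camera with the preset correlation. With an estimated correlation it passed in none of these cases (camera adjusted p from 0.37 to 0.78). Over all genes tested 1 member was called, Lef1, and 3 were called when adjusted over the list alone, Lef1, Fgf5 and Otx2. The last pair is named after its values were seen. Fgf5, a growth factor of the post-implantation epiblast, had 0, 3 and 2 counts in wild type and 94, 53 and 44 in Yaf2KO (log2 fold change 3.18, SE 0.82, adjusted p = 0.142 by edgeR over all genes). Its log2 fold change was 2.66 without wild type 1 and 4.13 without wild type 2. Otx2, a transcription factor of the exit from naive pluripotency, had 32, 32 and 83 against 1980, 609 and 404 (2.09, SE 0.48, adjusted p = 0.111 by edgeR). The other 5 tested members were not called: Pim2 (0.72, SE 0.36) and Zic2 (0.72, SE 0.38) lay above the typical listed gene, and Zic5 (0.09, SE 0.35), Pou3f1 (-0.09, SE 0.35) and Car14 (-0.08, SE 0.71) close to it.

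WNT and TGF-beta response genes showed the same split between a few members and the rest. Of 25 fixed symbols 8 were listed and 7 tested, and the list lay above the others by camera (adjusted p = 0.00988, median 0.58), with adjusted p = 0.304 with an estimated correlation and 0.188 by fry. Its call was also lost without wild type 3 (camera adjusted p = 0.154) and without Yaf2KO 2 (0.128; range with single libraries left out 0.00308 to 0.154). Lef1 was called over all genes and also when adjusted over the list alone. It is also a member of the primed epiblast list, so the results of these lists are not independent. The WNT feedback genes Axin2 (0.58, SE 0.43) and Notum (0.02, SE 0.53) were not called. Neither were T (1.55, SE 0.86), Sp5 (0.49, SE 0.65) and Id3 (-0.16, SE 0.45).

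Naive pluripotency genes as a list did not stand apart (8 of 31 symbols listed and tested, camera adjusted p = 0.889, median -0.13). Klf4 was the 1 member called when adjusted over the list alone, with 148, 94 and 160 counts in wild type and 5073, 1120 and 507 in Yaf2KO (log2 fold change 1.61, SE 0.45, adjusted p = 0.177 by edgeR over all genes). Without Yaf2KO 1 its log2 fold change was 1.0 (SE 0.34). Nanog (-0.09, SE 0.33), Klf5 (-0.21, SE 0.37) and Tet2 (0.03, SE 0.40), a 5-methylcytosine oxidase also on the DNA methylation list, moved as the typical listed gene did. At equal depth, which leaves the shift common to the list (2.16 log2 units) in place, Nanog came to 2.23 and Klf5 to 2.19. The turned sign of such values close to 0 follows from that scaling and says nothing further about these genes.

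Most listed genes that Polycomb complexes are known to silence had few reads. As a reference, 808 of the 21951 annotated protein-coding genes were listed. The listed shares of the non-Hox target regulators, Hox genes and germline genes below were larger than that. The listed share of the PRC1 components was smaller. Enrichment of these classes was not tested, because the genes that could have entered the list are unknown. Of 65 non-Hox target regulators 10 were listed, all 10 with more reads in Yaf2KO and 5 with complete separation of the libraries. Only 4 had enough reads to be tested (camera adjusted p = 0.0821, median 0.93; 0.0427 without wild type 1, where 6 were tested, but adjusted p = 0.37 there with an estimated correlation), with 0 called over all genes. Among them was the eye and neural factor Pax6 (35, 47 and 28 counts against 273, 430 and 105, log2 fold change 0.81, SE 0.55). Of 39 Hox genes 4 were listed, Hoxb1, Hoxb3, Hoxb5 and Hoxb8, and 0 could be tested. Hoxb1 had 0, 1 and 0 counts in wild type and 8, 7 and 5 in Yaf2KO, and Hoxb3 had 1, 0 and 0 against 0, 4 and 7. Of the germline genes, another class silenced by variant PRC1, 7 of 44 were listed and 5 tested (adjusted p = 0.889, camera direction lower but median 0.18 and mean 0.13). The meiotic genes Hormad1 (44, 22 and 23 against 392, 69 and 19) and Stra8 (20, 16 and 34 against 221, 113 and 41) had log2 fold changes of -0.15 (SE 0.66) and 0.18 (SE 0.49). Bcor was the 1 listed gene of 35 PRC1 components (log2 fold change -0.42, SE 0.34).

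Lineage and cell type markers gave 0 calls over all genes or over the list alone. Mesoderm and primitive streak genes had 13 of 35 members listed and 7 tested (camera adjusted p = 0.541, median 0.77), with Wnt3 at 0.77 (SE 0.67) and Sp5 at 0.49 (SE 0.65). Without Yaf2KO 1 this list passed the threshold (camera adjusted p = 0.00356, but adjusted p = 0.336 with an estimated correlation). The feeder markers had a camera direction of higher in that setting as well (adjusted p = 0.177). Neuroectoderm genes had 5 of 35 listed and 3 tested (adjusted p = 0.889, median -0.13 but camera direction higher), with the intermediate filament gene Nes, the member with the most reads, at -0.13 (SE 0.43). Single tested members represented primitive endoderm (Sox7, -0.42, SE 0.55), trophectoderm (Tfap2c, 0.20, SE 0.35), 2-cell-like cells (Fgf1, 0.36, SE 0.54) and muscle (Acta1, -0.07, SE 0.65). The markers of the fibroblasts on which the cells grew had 5 of 36 members listed and 3 tested (adjusted p = 0.889, camera direction lower but median 0.20). Interferon-stimulated genes had 6 of 30 listed and 5 tested (adjusted p = 0.541, median 0.43), with Gbp2 at 0.31 (SE 0.48) and Oasl2 at 0.43 (SE 0.44). Glycolysis and hypoxia genes had 2 of 31 listed, Slc2a3 (0.13, SE 0.32) and Pfkp (-0.29, SE 0.36), and the sex-linked markers only Tsix (7, 3 and 7 counts against 18, 9 and 5). The lists of PRC2 components, MYC-associated growth, proliferation, p53 targets, apoptosis, imprinted genes, the integrated stress response, the unfolded protein response, cholesterol biosynthesis, oxidative phosphorylation and FGF-ERK response had 0 members among the listed genes.

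The Yaf2KO libraries differed from one another more than the wild-type libraries did. The biological coefficient of variation was 0.326 within wild type and 0.602 within Yaf2KO. Pearson's r of scaled log2 values, across genes, ran from 0.907 to 0.946 between wild-type libraries and was 0.768 between Yaf2KO 1 and 3, lower than any pair of different genotypes (0.829 to 0.906). It was 0.834 between Yaf2KO 1 and 2 and 0.885 between Yaf2KO 2 and 3, within that range. The first principal component (41.3% of the variance) did not group the libraries by genotype. Wild type 1 to 3 (-4.822, -2.525 and -4.148) lay between Yaf2KO 1 (-12.07) and Yaf2KO 2 and 3 (6.513 and 17.05). In raw counts Yaf2KO 1 was the highest of the 3 for 138 of the 161 genes with a mean count of at least 100, so the lists were compared after scaling, as medians over members with a mean count of at least 10, relative to the wild-type mean. Naive pluripotency genes had medians of 0.32, -0.07 and -0.72 log2 units in Yaf2KO 1, 2 and 3, and germline genes 0.75, -0.35 and -1.43. Primed epiblast genes had 0.43, 0.24 and 1.30, and mesoderm genes -1.03, 0.86 and 0.97. Among the feeder markers, the smooth muscle gene Tagln had 1200, 900 and 780 counts in wild type and 2493, 7092 and 2428 in Yaf2KO, and the collagen gene Col1a1 252, 285 and 210 against 290, 1487 and 742. Feeder markers thus stood above the list in Yaf2KO 2 and below it in Yaf2KO 1, by medians of 0.93 and -1.69 log2 units.

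**Figure D3:**
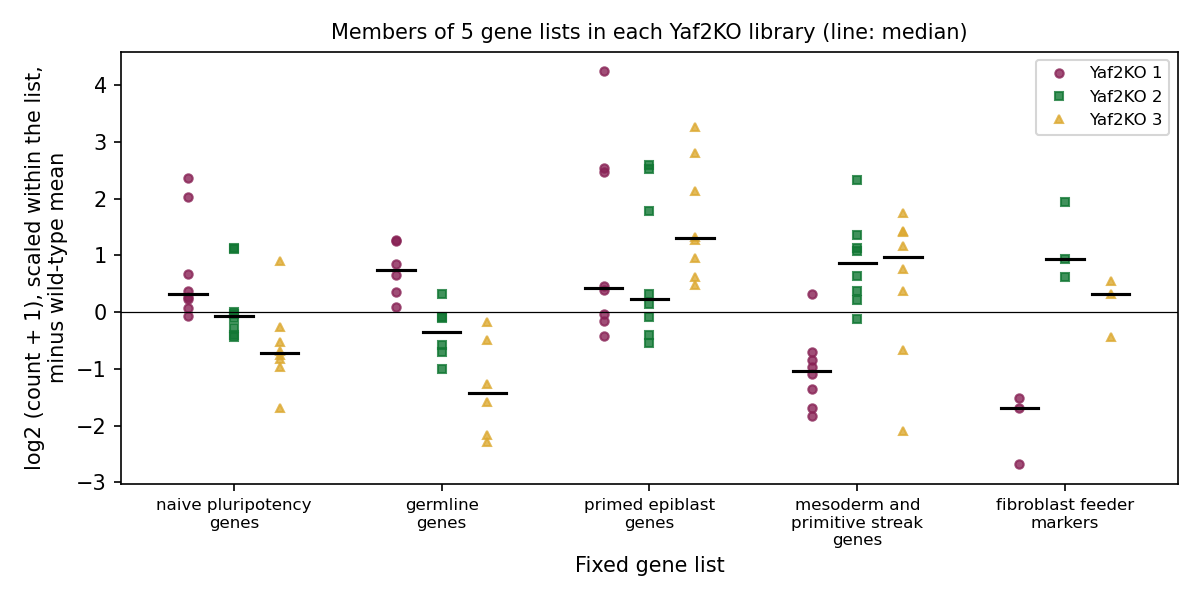
Members of 5 gene lists with a mean count of at least 10 (points) in each Yaf2KO library, as log2 of count plus 1 scaled on the listed genes minus the wild-type mean (y axis, log2 units), with a line at each median. Naive pluripotency medians are 0.32, -0.07 and -0.72 in Yaf2KO 1, 2 and 3, and mesoderm medians -1.03, 0.86 and 0.97.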

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

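Equal depth, scaling to the sum of the listed genes and the leave-one-out values of the raw counts were chosen after the data were seen; the other alternatives were planned. Lef1, Csn3 and Wnt8a kept a positive log2 fold change under every alternative run, from 2.75 to 5.97, 3.05 to 5.25 and 3.09 to 5.38. The count of 3 called genes was 3 with DESeq2 size factors and with scaling to the listed totals, and 2 with upper-quartile factors. It came to 10 with the DESeq2 Wald test (2 adjusted p-values not given by the tool), 15 without a low-count filter and 15 with a mean CPM of at least 1. It fell to 0 with limma-voom, where 14 genes had an unadjusted p under 0.05, and to 0 at an adjusted p under 0.01. It rose to 314 at equal depth. The counts at 2-fold or more were identical in each case: 10, 15, 15, 0 and 314. Leaving out single libraries gave 0 to 11 calls, the same range at 2-fold; 0 calls came without any single wild-type library (17, 16 and 21 genes at an unadjusted p under 0.05), 1 without Yaf2KO 2 and 11 without Yaf2KO 1. More genes are tested without a filter, and equal depth leaves the common shift in place by construction; the cause was not tested for the other differences.

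With the replicate number as a paired block there were 0 calls (18 genes at an unadjusted p under 0.05), also 0 at 2-fold, and 2 lists. The numbers are only shared, and no label says that they mark pairs. Deviations of same-numbered libraries correlated at 0.04, 0.18 and 0.17 over genes, and those of differently numbered ones at -0.35 to 0.25. Wild type 1 correlated best with Yaf2KO 2 (0.25), whereas wild type 2 and 3 correlated best with the Yaf2KO library of the same number. These values do not decide whether the libraries were paired. The 2 lists past the threshold fell to 0 with an estimated correlation and to 0 with fry, and ranged from 1 to 3 with single libraries left out (1 without wild type 3 or Yaf2KO 2). They numbered 2 under the other scalings, filters and limma-voom. The DESeq2 test was not run for lists. Among the raw counts, listed genes with a higher mean in Yaf2KO numbered 1302 to 1577 with single libraries left out, well-counted ones 158 to 161, and genes with every Yaf2KO count above every wild-type count 487 to 884, the last without Yaf2KO 3.

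Over the genes followed across all alternatives, 332 log2 fold changes kept direction and call, 45 passed the threshold only under the alternative, 19 lost it and 49, all of genes that were not called, changed sign. At equal depth the sign turned for Acta1 (2.03), Bcor (1.85), Hormad1 (2.43), Klf5 (2.19), Nanog (2.23), Nes (1.75), Pfkp (2.03) and Sox7 (1.83). Without a filter, and likewise with the mean CPM of at least 1, it turned for Acta1 (0.20), Hormad1 (0.18), Klf5 (0.10), Nanog (0.26), Nes (0.14) and Pfkp (0.024). With limma-voom it turned for Col1a1 (-0.64), Sp5 (-0.088), Tagln (-0.16) and Tet2 (-0.028), with the block for Col1a1 (-0.42), Tagln (-0.035) and Tet2 (-0.082), with upper-quartile factors for Tet2 (-0.078) and with listed totals for Col1a1 (-0.0067). Leaving out single libraries gave log2 fold changes from the lowest to the highest of Acta1 -1.07 to 0.39, Col1a1 -0.36 to 0.55, Gbp2 -0.057 to 0.67, Hormad1 -1.12 to 0.25, Nanog -0.32 to 0.15, Nes -0.40 to 0.22, Slc2a3 -0.18 to 0.30, Sp5 -0.015 to 0.96, Tagln -0.36 to 0.63, Tet2 -0.43 to 0.33 and Tfap2c -0.072 to 0.42. At equal depth the signs turned because that setting leaves the shift common to the list (2.16 log2 units) in place. The cause was not tested for the other sign changes, each smaller than 2 standard errors. Yaf2 and its neighbours have no value under any setting. FPKM alternatives were not run, since the values are counts. What limits all of these results is that library totals were not used and that 469 of 1653 genes have fewer than 10 reads in all.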

Other observations

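The edgeR and DESeq2 fits were planned; the choice of genes and families below and the tests of the 3 patterns were made after the results were seen. Some gene families outside the fixed lists are given as values; they were picked after the values were seen and not tested for enrichment. More reads in Yaf2KO is no mark of a family here, since 1524 of 1653 genes had them, so values relative to the list are given. Of 6 tested Platr genes, long non-coding RNAs of pluripotent cells, 4 lay above 0 and 2 below, led by Platr13 (23, 22 and 8 counts against 363, 356 and 264, log2 fold change 2.30, SE 0.60, adjusted p = 0.142 by edgeR). Of the 4 listed metallothioneins, which bind zinc and other metals, Mt1 and Mt2 lay above the typical gene (0.24 and 0.67) and Mt3 and Mt4 below it (-0.25 and -0.48), and none of the 4 was called. Of the Wnt ligands 3 of 4 tested lay above 0. Of 12 listed replication-dependent histone genes 1 could be tested, Hist1h3c, at a log2 fold change of -0.0077. At equal depth the tested Platr, metallothionein, Wnt and histone genes all have positive values. Halr1, a non-coding RNA next to the Hoxa cluster, had 3, 1 and 1 counts in wild type and 166, 76 and 15 in Yaf2KO (log2 fold change 3.27, SE 0.76, adjusted p = 0.111 by edgeR, and 4.04 without wild type 1), and Gfra1, a GDNF co-receptor, 11, 10 and 16 against 213, 266 and 258 (2.58, SE 0.62, adjusted p = 0.113 by edgeR). Both were called by DESeq2.

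Of 7 listed genes of the X-linked Rhox homeobox cluster 2 could be tested, Rhox5 (log2 fold change relative to the list 0.10, SE 0.55) and Rhox1 (-0.19, SE 1.07), and neither was called. In raw counts Rhox5 had 241, 234 and 210 counts in wild type and 2788, 1182 and 131 in Yaf2KO, and Rhox1 14, 8 and 10 against 174, 14 and 0. The X-linked gene Pnma5 had 193, 147 and 157 against 1943, 55 and 19. Of the 161 genes with a mean count of at least 100, 12 had fewer reads in Yaf2KO 3 than in every wild-type library. Wild type 2 and 3 departed from the other wild-type libraries with exonic length (Spearman's rho across 480 genes 0.30 and -0.23), whereas the Yaf2KO libraries did not (-0.02 to 0.02).

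The first pattern is that nearly every listed gene was higher in Yaf2KO. Among the 161 genes with a mean count of at least 100, 0 had a lower sum in Yaf2KO. That count does not decide whether the genes were chosen for higher values in Yaf2KO, since a common shift from depth would also leave few lower sums. For the shift common to all listed genes (4.46-fold), deeper Yaf2KO libraries and a real increase of the chosen genes cannot be told apart here without library totals. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real split gave 3 calls and the highest other 0 (1 split as large, the real one), equally at 2-fold (1 split). For the gene lists the real split gave 2 and the highest other 3, and 5 of the 10 splits gave at least as many.

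The second pattern is in the 2 listed Y-linked genes. Zfy1 (Y:725128-797409) had 8, 8 and 6 counts in wild type and 837, 1 and 0 in Yaf2KO, and Uba1y (Y:818649-844224) had 108, 60 and 93 against 978, 13 and 7. Depth does not account for it, since Uba1y in Yaf2KO 2 and 3 was at most 0.149 of its wild-type mean while the median listed gene with a mean count of at least 100 was at 3.57 and 1.71 of its own. Nor does RNA from feeder fibroblasts with 1 fixed ratio of Uba1y to Col1a1 in every culture, as that ratio of counts varied 386-fold between libraries. Feeders that differed between the cultures were not tested and stay open. Cultures that differ in Y-linked expression stay open as a hypothesis. Both genes were under every wild-type count in Yaf2KO 2 and 3, but 2 genes are too few to tell. The X-linked gene Pnma5, given above, was also under every wild-type count in Yaf2KO 2 and 3 and above each in Yaf2KO 1. The pattern is therefore not limited to Y-linked genes, and no biological explanation was tested.

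The third pattern is the spread among the Yaf2KO libraries. A difference in depth removed by scaling would not lower the correlation between Yaf2KO 1 and 3 to 0.768, below every wild-type pair although both hold more counts. From Yaf2KO 3 to Yaf2KO 1 the naive pluripotency members shifted by a median of 1.28 log2 units and the mesoderm members by -2.17, a difference of 3.45. This sets 2 single libraries against each other for lists picked after the spread was seen, so it has no replicate check. A different share of feeder fibroblasts stays open: the feeder markers shifted by a median of -1.83, in the direction of the mesoderm members, and which cells the mesoderm reads came from was not tested. Also open, and not decided by these values, is a second candidate explanation, that the 3 Yaf2KO cultures held cells in different states. Under it Yaf2KO 1 would be closer to naive pluripotency than Yaf2KO 3, and Yaf2KO 2 and 3 would have more mesoderm-like expression. Meox1 (38, 14 and 1 counts) is an exception among the mesoderm genes. Against the wild-type mean, though, the Yaf2KO 1 median was 0.43 for primed epiblast genes, next to 0.32 for naive genes. The primed epiblast median was highest in Yaf2KO 3 (1.30). Whether the cultures are separate clones is not given in the labels, and the pattern was found in the same data.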
